A study of Drosophila melanogaster with 144 samples.

How the data were processed

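RNA from heads of adult virgin Drosophila melanogaster was sequenced as strand-specific poly(A) libraries. Per the labels, the flies belonged to DGRP_892, an inbred line of the Drosophila Genetic Reference Panel with a long circadian period, or to Canton-S B, a line with a period of 24 h. They were kept for 3 days in cycles of 12 h light and 12 h darkness and then for 3 days in constant darkness. Heads were frozen every 2 h at 12 circadian times (CT), and each library held RNA of 150 heads plus ERCC spike-in transcripts. Flies came from 2 incubators with opposite light cycles, and the labels do not say which circadian times each incubator gave. The 144 libraries form 48 groups of 3 (2 genotypes, 2 sexes and 12 times). The labels number the replicates 1 to 3 and state that the collection was run 3 times.

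The submitters' processing notes name FastQC 0.11.5, STAR 2.5.3a and featureCounts 1.5.2. Per the labels, reads were mapped to release 6 of the FlyBase genome together with the ERCC sequences and counted per gene. The strand setting of the counting is not given in the sources used here, so antisense and overlapping genes are uncertain, as are near-identical copies such as the Hsp70 genes, Cyp12d1-d and Cyp12d1-p, or Amy-p and Amy-d. The labels give 125-bp reads and 20 to 25 M pairs in 1 text, and 76-bp reads and at least 12 M pairs in another. The deposited count table holds the authors' unnormalized read counts for 17381 genes and 92 ERCC transcripts. It has 1 further column, which is empty and was not used. A second deposited table holds the authors' batch-corrected, TMM-normalized values for 11525 genes, treated as a score without fixed range because 3.31% of its values lie below 0. How the authors corrected for batches is not given in the sources used here. Consecutive runs of 24 library numbers explained a median of 94.6% of the variance of its difference from the scaled counts over 5160 genes. This table served only as an alternative, with values below 0 set to 0 and log2(value + 20) tested by limma-trend, so that its fold changes understate those of low genes.

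Gene symbols and coordinates were taken from the Ensembl release 115 annotation of the FlyBase release 6 assembly. It named 17239 of the 17381 genes, and the other 142, of which 93 were tested, keep their identifiers. The ERCC transcripts took 0.387% of all counts and were left out of library sizes and tests. Genes were kept by filterByExpr on the 48 groups (minimum count 10, minimum total 15), which left 10894 genes with 99.97% of the gene counts. The main tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, glmQLFit with robust dispersions and glmQLFTest, with Benjamini-Hochberg adjustment over the 10894 genes and a threshold of 0.05. All 144 libraries entered each fit, so that all groups shared 1 estimate of the spread. Effects of genotype and sex and their interaction were contrasts of 48 group means. Rhythms were tested with a 24-h cosine and sine for each genotype and sex, as 2 coefficients averaged over the sexes, and genotype by time and sex by time as differences of these coefficients. Amplitudes are the log2 distance from mean to peak of the fitted curve. Levels are counts per 1e6 gene counts (CPM) with the SD over libraries.

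For peak times and amplitudes of the core clock genes, each genotype was also treated as 6 series of 12 libraries (3 replicate numbers in 2 sexes). Cosines were fitted by least squares to log2 CPM with a prior count of 2. The 6 series of each genotype were compared by a two-sided exact permutation test over 924 splits, and paired medians by an exact two-sided sign-flip test over 64 flips, whose smallest p is 0.0312. The 26 gene lists were fixed beforehand and cover the core clock, clock regulators, rhythmic output genes of the head known from earlier work, clock neuropeptides, phototransduction, eye pigment, ion channels and sleep genes. They also cover immunity, detoxification, heat shock, odorant binding, sex markers, dosage compensation, fat body, neurons, glia, haemocytes, tissues of thorax and abdomen, metabolism, ribosomal proteins and mitochondrially encoded genes. Lists were tested with camera (limma 3.58.1, preset correlation 0.01) for genotype and sex, and with a one-sided Fisher exact test against all genes tested for rhythms, adjusted over the lists. Camera was repeated with an estimated correlation, and fry was run beside it. Fry's directional p tests whether the genes of a list move, on balance, one way, and its mixed p whether they change in either direction. Neither compares a list with other genes. DESeq2 1.42.0 served as an alternative, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

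Before the data were examined, the groups, tests, gene lists, most alternatives and the rule for named genes were fixed. The rule takes the 10 highest and 10 lowest fold changes of genotype and of sex among genes past 0.05 with at least 5 CPM in the higher group and the same sign in all 24 pairs of groups. It takes the 10 largest amplitudes in each genotype and the 10 largest genotype-by-time distances, with at least 5 CPM, and the 5 largest values for genotype by sex and sex by time. It adds every core clock gene, w, the 3 yolk protein genes and both roX genes, and from each list up to 4 members past the threshold and up to 2 that were not. Genes named outside it were chosen after their values were seen, and the text says so.

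Scripts were tested on simulated counts for the 10894 genes. For genotype, 99% of 100 genes changed 1.5-fold and 100% of 100 changed 2-fold were recovered, and 1.97% of calls were false. For sex, both figures were 100%, and 5.66% of calls were false. For the Canton-S B rhythm, 69% of 100 genes with an amplitude of 0.2 and 98% of 100 with 0.5 were recovered, with 7.73% false calls. For genotype by time, 16% of 100 differences of 0.2 and 90% of 100 differences of 0.5 were recovered, with 5.36% false calls. No rhythm was simulated in DGRP_892 and no difference for sex by time or genotype by sex, and each of these tests made 0 calls. The simulated counts had 1 common dispersion and no runs, replicate effects or outlying libraries. These figures therefore check the scripts and do not give the error rates of the real libraries.

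The labels make the replicate number a shared run of the whole procedure, and libraries with the same number deviated from their group means together more than others (mean correlation 0.0533 against -0.0265). Libraries sharing a block of 12 library numbers (0.123 against -0.0101) or a run of 24 (0.111 against -0.021) did so more strongly, so the replicate number is not the main shared structure. For numbers 1, 2 and 3, the mean deviations of the 2 genotypes correlated at 0.502, 0.0551 and 0.244, and those of unlike numbers at -0.388 to 0.118, so that number 2 showed no pairing of its own in this check. Because of the labels the number was treated as pairing the libraries, with the fit that holds it as a block as an alternative. Over 144 pairs of replicates the lowest chi-square per gene was 7.37, so no library was a second copy of another in its own group; pairs across groups were not compared. Other alternatives were RLE scaling, ERCC scaling, no filter on low counts, DESeq2, blocks of 12 library numbers (a stand-in for extraction groups), each replicate number left out and the authors' batch-corrected values. For rhythms, a term for the earlier against the later 12 h, a 12-level time factor and a 28-h cosine in DGRP_892 were added. Chosen after seeing the data were fits without 5 doubtful libraries or without each of them, fits within the 48 deeper and the 96 shallower libraries, combined blocks, and paired sign-flip tests of the projected amplitudes and of the clock genes. A library was called doubtful where its mean over 1 of 6 lists (gut, testis and accessory gland, ovary, flight muscle, haemocytes, heat shock) stood at least 2 log2 units and 8 median absolute deviations above the median of its genotype and sex.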

Results

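The data comprised 144 head libraries, 72 of each genotype and 72 of each sex, with 3 libraries for each genotype, sex and circadian time. Gene counts per library ran from 11.7 M to 37.3 M (in units of 1e6), with a median of 15.2 M. The labels' library numbers split by depth: 48 libraries, all in runs 1 and 4 of 6 runs of 24 numbers, held 25.5 M to 37.3 M counts, and the other 96 held 11.7 M to 18 M. Both depth classes contained both genotypes, both sexes and every time, so comparisons were repeated within each class. There, genotype, sex and their interaction were tested on the means of the 24-h cosine fits instead of the 48 group means. The 10 most abundant genes took 18.6% ± 2.99 of the counts in DGRP_892 and 15.0% ± 2.39 in Canton-S B (SD, n = 72 each). On the first principal component, with 33.1% of the variance, genotype explained a share of 0.994, and on the second, with 15.2%, sex explained 0.922. The third component, with 7.93%, followed the runs of 24 library numbers (share 0.71).

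**Figure D1:**
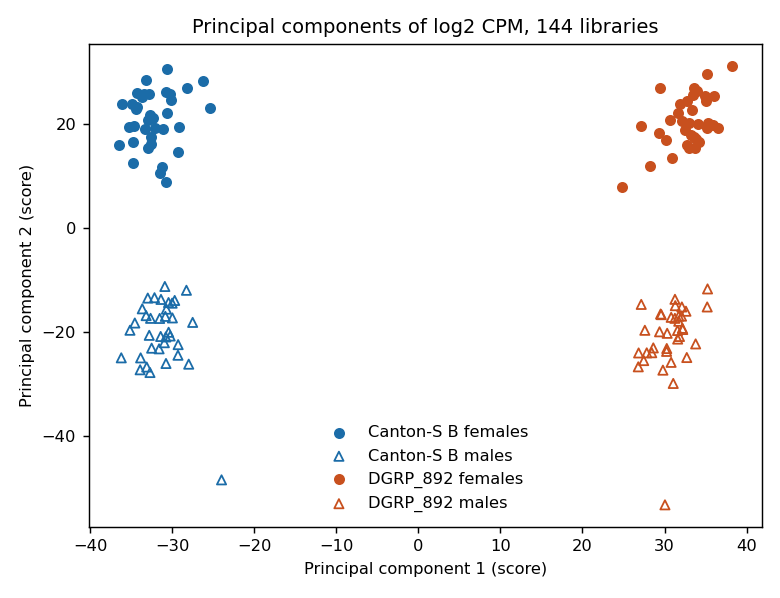
First and second principal components of log2 CPM for the 144 libraries, 1 point per library, marked by genotype and sex. The first axis (33.1% of the variance) separates the genotypes and the second (15.2%) the sexes.

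Genes with known levels followed the labels. Expression of w, an eye pigment transporter gene whose mutant allele the labels give for the Canton-S B cultures, was 0.265 ± 0.147 CPM in Canton-S B females and 0.206 ± 0.128 in males. In DGRP_892 it was 28.9 ± 3.64 and 30.6 ± 3.71 (SD, n = 36 each). The dosage compensation RNA roX1 stood at 1690 ± 269 CPM in Canton-S B males and 1760 ± 226 in DGRP_892 males, against 15.3 ± 15.6 and 20.8 ± 7.9 in females. Its partner roX2 stood at 44 ± 15.2 and 44.6 ± 13.8 CPM in males, and at 0.430 ± 0.432 and 0.263 ± 0.264 in females. The yolk protein gene Yp1 reached 27200 ± 8170 CPM in Canton-S B females and 44300 ± 9740 in DGRP_892 females. In males it averaged 443 ± 641 and 214 ± 412 CPM, with single libraries up to 2620 and 1840.

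The genotype comparison asked which head transcripts differ between the long-period line and Canton-S B. Expression differed in 7363 of 10894 genes, of which 3380 were higher and 3983 lower in DGRP_892. At least 2-fold differences were found for 517 genes that were higher and 313 that were lower. The cytochrome P450 gene Cyp6a17 (FBgn0015714, chromosome 2R, 14873953 to 14875739) was higher in DGRP_892, at 125.6 ± 12.4 against 0.980 ± 0.399 CPM (SD, n = 72 each), a log2 fold change of 7.01 ± 0.06 (SE). Among the genes lower in DGRP_892, CG14419 (FBgn0029639, X, 2885186 to 2885914) was at 3.84 ± 2.44 against 161 ± 89.2 CPM, a log2 fold change of -5.36 ± 0.10 (SE).

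Besides Cyp6a17 and w (log2 fold change 6.98 ± 0.06, SE), the 10 genes highest in DGRP_892 by the naming rule (at least 5 CPM and 1 direction throughout) were CG45072 (8.84 ± 0.15), lncRNA:CR45997 (7.23 ± 0.12), CG2861 (6.60 ± 0.08), CG31683 (6.60 ± 0.11), asRNA:CR44030 (6.30 ± 0.14), CG11893 (5.96 ± 0.07), the carbonic anhydrase gene CAH5 (6.13 ± 0.15) and the glycosyltransferase gene Ugt37B1 (5.88 ± 0.10). CG45072 averaged 6.30 ± 2.65 CPM in DGRP_892 and 0.0122 ± 0.029 in Canton-S B, and its fold therefore rests on very few reads in Canton-S B. Besides CG14419, the 10 lowest were Osi2 (-5.22 ± 0.11), asRNA:CR45822 (-4.65 ± 0.09), lcs (-4.49 ± 0.63), asRNA:CR45835 (-4.33 ± 0.08), CG34456 (-4.18 ± 0.07), asRNA:CR45600 (-4.02 ± 0.09), CG30054 (-3.76 ± 0.09), CG8757 (-3.70 ± 0.06) and phr (-3.33 ± 0.06). Osi2 is a gene of the Osiris family and phr encodes a DNA photolyase. Adjusted p lay between 2.51e-109 for w and 2.32e-10 for lcs (edgeR quasi-likelihood test, Benjamini-Hochberg), and all 20 had 1 direction in all 24 pairs of sex and time groups. The antisense transcripts are uncertain, since the strand setting of the counting is not known.

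For this genotype effect, the same test gave 6060 genes in males and 6565 in females. Of 4927 genes past the threshold in both, 4834 had the same direction, and fold changes correlated at 0.91 across genes, which are not independent replicates. Within the deeper libraries 5374 genes were past the threshold, and within the shallower ones 6639. With the ERCC transcripts as scale the count was 3605, and with the authors' batch-corrected values 345 genes were past 2-fold instead of 830.

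Detoxification genes were mostly higher in DGRP_892. Of 61 P450 and glutathione transferase genes measured, 46 were higher and 11 lower (camera, adjusted p = 1.15e-13, and adjusted p = 0.0694 with an estimated correlation). Cyp12d1-d stood at 4.38 against 0.00424 CPM (adjusted p = 5.41e-48), Cyp309a2 at 34.5 against 0.840 (log2 fold change 5.69 ± 0.08) and Cyp4p2 at 10.6 against 0.277 (5.25 ± 0.07), whereas GstE4 (-0.05 ± 0.15) and GstD10 (0.00 ± 0.06) were not past the threshold. Cyp12d1-d has a near-identical copy, Cyp12d1-p, whose reads the counting could split. Fat body genes were higher in 15 of 17 cases and lower in 1 (adjusted p = 1.19e-06, and adjusted p = 0.101 with an estimated correlation). They were led by the storage protein gene Lsp2 (4.39 ± 0.22), Obp99b (2.75 ± 0.11), Fbp1 (2.42 ± 0.18) and the glucosidase gene tobi (1.71 ± 0.13), and FASN1, the fatty acid synthase gene, stood at 0.06 ± 0.03. Lipid and carbohydrate genes were higher in 13 of 19 cases and lower in 2 (adjusted p = 0.00322, and adjusted p = 0.334 with an estimated correlation). Among them were the maltase gene Mal-B1 (3.94 ± 0.07), the amylase gene Amy-p (3.79 ± 0.15) and the lipase gene Lip3 (0.92 ± 0.14). Of these 19 genes, 10 are also members of another list.

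Of 11 flight muscle genes, 10 were lower and 1 higher in DGRP_892 (adjusted p = 0.00222, and adjusted p = 0.101 with an estimated correlation). The flight muscle actin gene Act88F stood at 3.14 against 11.8 CPM (-1.94 ± 0.07), the troponin gene TpnC41C at 10.0 against 28.5 (-1.48 ± 0.08) and Mlp84B at 177 against 299 (-0.74 ± 0.03). Of 6 ovary genes measured, of 20 listed, 4 were higher and 1 lower (adjusted p = 0.0251, and adjusted p = 0.101 with an estimated correlation). These were eggshell genes at low levels, such as Cp7Fa at 5.44 against 1.31 CPM and Cp7Fb at 3.20 against 0.933. With the estimated correlation 0 of the 26 lists passed camera for genotype, against these 5 with the preset correlation. Fry called 19 lists by its directional p, which does not compare a list with other genes.

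The other 21 lists were not past the threshold in camera, yet many single members were. All 8 core clock genes differed: vri (0.70 ± 0.05) and tim (0.37 ± 0.02) were among 6 that were higher, and Clk (-0.47 ± 0.04) and the photoreceptor gene cry (-0.45 ± 0.04) were lower (list adjusted p = 0.385); with ERCC scaling 3 were higher and 2 lower. Of 26 clock regulators, 4 were higher and 12 lower, among them kay (-0.24 ± 0.04), whereas the kinase gene sgg stood at -0.06 ± 0.05; with ERCC scaling 0 were past the threshold in the edgeR test. Of 22 head output genes, 6 were higher, including Cyp4e3 (3.51 ± 0.08), and 8 lower, including CG2121 (-1.30 ± 0.03), with a median of 0.0239 and, with ERCC scaling, of -0.000932. Of 20 neuropeptide and receptor genes, 5 were higher, including CNMa (0.94 ± 0.10) and the PDF receptor gene Pdfr (0.53 ± 0.03), and 7 lower, including Mip (-0.41 ± 0.02). In phototransduction, 9 of 24 were higher and 12 lower. The opsin genes Rh4 (1.13 ± 0.03), Rh6 (0.64 ± 0.04) and ninaE (0.51 ± 0.03) were higher, and norpA stood at 0.02 ± 0.05. Of 16 eye pigment genes, 7 were higher, including v (1.23 ± 0.04) and cn (1.62 ± 0.13), and 2 lower (median 0.0167, and -0.0124 with ERCC scaling). Of 22 ion channel and sleep genes, 2 were higher and 11 lower, including the dopamine transporter gene DAT (-0.72 ± 0.03).

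Of 30 immune genes, 16 were higher, including the defensin gene Def (1.89 ± 0.09), and 7 lower, including the stress-induced Turandot genes TotA (-2.13 ± 0.12), TotX (-1.83 ± 0.09) and TotM (-1.79 ± 0.13). Of 34 odorant-binding genes, 11 were higher, including Obp99d (3.41 ± 0.10), and 10 lower, including Obp83cd (-1.65 ± 0.06), against 8 higher and 9 lower with ERCC scaling. Of 19 heat-shock genes, 9 were higher and 5 lower, with near-identical Hsp70 copies in opposite directions (Hsp70Bc 2.12 ± 0.33, Hsp70Ba -2.03 ± 0.38). Haemocyte genes were lower in 6 of 10 cases and higher in 1, with the phagocyte receptor gene NimC1 at 42.8 against 83.5 CPM (-0.96 ± 0.04). Neuronal genes were lower in 9 of 14 and higher in 0, including Gad1 (-0.53 ± 0.03), and glial genes lower in 6 of 10 and higher in 1. The remaining counts, higher and lower, were 3 and 2 of 6 male markers, 1 and 1 of 6 female markers, 2 and 3 of 7 dosage compensation genes (median 0.00444, and -0.0238 with ERCC scaling) and 5 and 3 of 12 glycolysis genes (0.0235, and -0.00282 with ERCC scaling). For testis and accessory gland they were 2 and 1 of 8 measured of 23 listed, for gut 3 and 0 of 12 measured of 23 listed, for ribosomal proteins 5 and 13 of 80, and for mitochondrially encoded genes 3 and 2 of 16.

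Adjusted over the list alone, the genotype counts were the same except for 14 clock regulators, 58 detoxification genes, 8 glial genes, 11 ribosomal protein genes and 4 mitochondrially encoded genes past the threshold. Median, mean and camera direction differed in sign for neuropeptides (median -0.01, mean 0.04), phototransduction (-0.05, 0.05), female markers (-0.11, 0.14), dosage compensation (0.00, -0.01) and testis and accessory gland (-0.18, 0.46). No other list median changed sign with ERCC scaling. That scaling left no list with more calls, with higher and lower counts of 42 and 8 for detoxification, 12 and 1 for fat body, 1 and 7 for flight muscle, 9 and 2 for lipid and carbohydrate genes and 4 and 0 for ovary. They were 3 and 5 for output genes, 3 and 3 for neuropeptides, 5 and 6 for phototransduction, 4 and 0 for eye pigment, 1 and 3 for ion channels, 14 and 6 for immune genes and 2 and 2 for heat shock. They were 0 and 4 for haemocytes, 0 and 2 for neurons, 1 and 5 for glia, 1 and 1 for glycolysis, 0 and 2 for ribosomal proteins and 0 and 0 for dosage compensation. They were 1 and 0 for each set of sex markers, 1 and 1 for testis and accessory gland, 3 and 0 for gut and 2 and 2 for mitochondrially encoded genes.

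**Figure D2:**
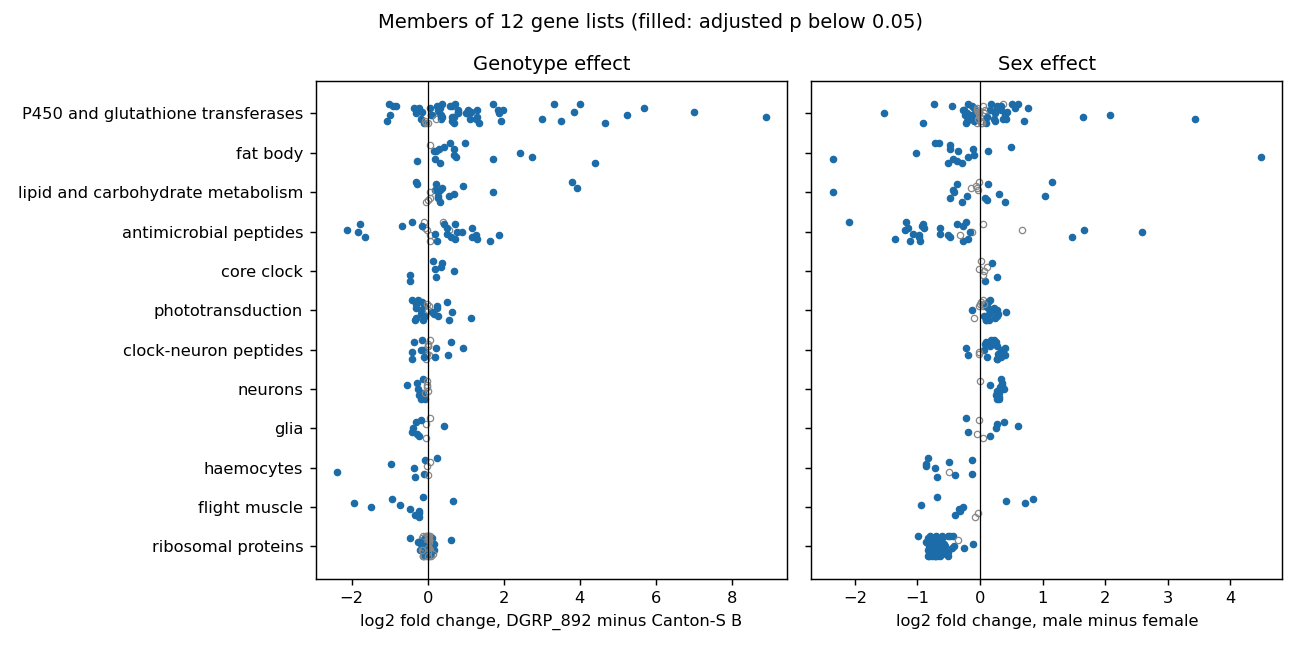
Log2 fold changes of the members of 12 gene lists for genotype (DGRP_892 over Canton-S B) and sex (male over female), 1 point per gene. Genotype medians run from -0.33 in flight muscle to 0.65 in detoxification; 79 of 80 ribosomal protein genes were lower in males, and so were 77 with ERCC scaling.

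The sex comparison asked which transcripts differ between male and female heads. Of 10894 genes, 7162 differed, 3919 being higher in males and 3243 higher in females. At least 2-fold differences were found for 154 genes higher in males and 144 higher in females. The odorant-binding gene Obp99b stood at 260 ± 269 CPM in males and 7.91 ± 6.81 in females (SD, n = 72 each). The yolk protein gene Yp1 (FBgn0004045, X, 10053811 to 10055498), was 186-fold higher in females. Its log2 fold change, male over female, was -7.54 ± 0.29 (SE).

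Highest in males by the same rule, on the log2 scale of male over female with its SE, were roX2 (7.18 ± 0.12), roX1 (6.66 ± 0.12), Obp99b (4.49 ± 0.11), Cyp4d21 (3.43 ± 0.06), Ugt37B1 (2.82 ± 0.13), sxe2 (2.79 ± 0.04), the storage protein gene Lsp1alpha (2.77 ± 0.14), TotX (2.59 ± 0.09), the glycine methyltransferase gene Gnmt (2.29 ± 0.09) and Cyp313a1 (2.07 ± 0.05). Highest in females, besides Yp1, were Yp2 (-7.27 ± 0.32), Yp3 (-6.76 ± 0.23), Obp99a (-6.74 ± 0.19), asRNA:CR45601 (-6.73 ± 0.13), FBgn0028519 (-4.50 ± 0.17), asRNA:CR45046 (-3.46 ± 0.11), rost (-3.14 ± 0.05), fit (-3.09 ± 0.12) and CG10814 (-3.01 ± 0.30). The gene asRNA:CR45601 lies within Yp1 on the other strand, so their reads cannot be told apart without the strand setting. Since asRNA:CR45046 overlaps fit on the same strand, no strand setting could separate reads from the stretch they share. Adjusted p for these 20 genes lay between 7.01e-82 for sxe2 and 6.89e-16 for CG10814 (edgeR quasi-likelihood test). For this sex effect, 4304 genes differed within the deeper libraries, and 6826 within the shallower ones. With ERCC scaling 5705 genes differed, of which 85.6% were higher in males against 54.7% in the main test. That scaling moved the median log2 fold change of all genes from 0.0262 to 0.225, and changes are given relative to the TMM scale. With the authors' batch-corrected values 94 genes were past 2-fold instead of 298.

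Ribosomal protein genes were lower in males in 79 of 80 cases and higher in 0, with a median of -0.69 (camera, adjusted p = 9.36e-38, and adjusted p = 0.028 with an estimated correlation). RpL41 stood at 548 CPM in males and 1092 in females (-0.99 ± 0.07), and RpS27A (-0.86 ± 0.04), RpLP1 (-0.85 ± 0.04) and RpL30 (-0.84 ± 0.03) followed. With ERCC scaling their median was -0.51 and 77 were lower. The dosage compensation list was higher in males in 6 of 7 cases and lower in 0 (adjusted p = 1.11e-06), including msl-2 (1.02 ± 0.03) and mof (0.28 ± 0.03). All 6 male markers were higher (adjusted p = 1.46e-11) and all 6 female markers lower (adjusted p = 9.97e-08). Haemocyte genes were lower in males in 9 of 10 cases and higher in 0 (adjusted p = 5.26e-06), such as the prophenoloxidase genes PPO2 (-0.87 ± 0.06) and PPO1 (-0.83 ± 0.07) and NimC1 (-0.86 ± 0.04). Neuropeptide genes were higher in 16 of 20 cases and lower in 2 (adjusted p = 0.00194), led by Dh31 (0.41 ± 0.02), the clock neuron peptide gene Pdf (0.40 ± 0.05), sNPF (0.34 ± 0.05) and Trissin (0.34 ± 0.04). These 6 lists were also past the threshold with an estimated correlation, and fry called 23.

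A further 6 lists passed only with the preset correlation. Neuronal genes were higher in males in 13 of 14 cases and lower in 0 (adjusted p = 0.000287, and adjusted p = 0.381 with an estimated correlation), such as VAChT (0.38 ± 0.07) and Snap25 (0.34 ± 0.04). Ion channel and sleep genes were higher in 19 of 22 and lower in 1 (adjusted p = 0.00384, and adjusted p = 0.552 with an estimated correlation), such as the GABA receptor gene Rdl (0.35 ± 0.06). Phototransduction genes were higher in 16 of 24 and lower in 1 (adjusted p = 0.0138, and adjusted p = 0.0607 with an estimated correlation), such as Rh6 (0.41 ± 0.04) and norpA (0.27 ± 0.05). Fat body genes were lower in 14 of 17 and higher in 3 (adjusted p = 0.00121, and adjusted p = 0.266 with an estimated correlation), such as tobi (-2.36 ± 0.13) and Apoltp (-0.72 ± 0.03). Immune genes were lower in 23 of 30 and higher in 3 (adjusted p = 0.011, and adjusted p = 0.614 with an estimated correlation). AttD was lower (-2.09 ± 0.22), whereas TotA (1.67 ± 0.12) and TotC (1.47 ± 0.13) were higher in males. Flight muscle genes were lower in 6 of 11 and higher in 3 (adjusted p = 0.0315, and adjusted p = 0.266 with an estimated correlation), with Mlp84B at -0.94 ± 0.03 and Act88F at 0.72 ± 0.07; with ERCC scaling the balance turned, with 2 lower and 3 higher.

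The other 14 lists did not pass. Higher and lower counts were 3 and 0 of 8 core clock genes, with per at 0.26 ± 0.05 and tim at 0.19 ± 0.02, 10 and 2 of 26 clock regulators, and 9 and 5 of 22 output genes. They were 23 and 17 of 61 detoxification genes (median -1.69e-05, and 0.192 with ERCC scaling), 12 and 10 of 34 odorant-binding genes, 1 and 13 of 19 heat-shock genes, 5 and 2 of 10 glial genes and 3 and 5 of 16 eye pigment genes (median -0.0041, and 0.195 with ERCC scaling, where 7 were higher and 0 lower). For testis and accessory gland they were 2 and 0 of 8, for ovary 1 and 3 of 6 (2 and 1 with ERCC scaling), for gut 3 and 0 of 12, for glycolysis 1 and 9 of 12 (median -0.136, and 0.0612 with ERCC scaling), and for lipid and carbohydrate genes 7 and 7 of 19 (-0.0438, and 0.155 with ERCC scaling). Of 16 mitochondrially encoded genes 0 were past the threshold in the edgeR test (median -0.00119, and 0.217 with ERCC scaling). Obp56e stood at 139.3 CPM in males and 1009 in females (-2.91 ± 0.04). Adjusted over the list alone, the counts were the same except for 2 core clock genes, 11 clock regulators, 7 eye pigment genes, 41 detoxification genes, 8 glial genes and 10 haemocyte genes. The camera direction and median differed in sign for detoxification (median 0.00, mean 0.14) and odorant binding (0.11, -0.15). No other list median changed sign with ERCC scaling in this comparison. With that scaling, higher and lower counts were 28 and 4 for detoxification, 17 and 0 for clock regulators, 5 and 0 for the core clock, 10 and 1 for output genes and 1 and 1 for glycolysis. They were 17 and 7 for odorant binding, 2 and 5 for heat shock, 6 and 0 for glia, 7 and 3 for lipid and carbohydrate genes and 4 and 0 for mitochondrially encoded genes. They were 0 and 6 for haemocytes, 3 and 7 for fat body, 3 and 18 for immune genes, 16 and 0 for neuropeptides, 13 and 0 for neurons, 20 and 0 for ion channels and for phototransduction, and 4 and 0 for gut. They were 2 and 0 for testis and accessory gland, 6 and 0 for dosage compensation and male markers, and 0 and 4 for female markers.

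The genotype difference itself depended on sex in 1399 genes, 80 of them by at least 2-fold. CAH5 was higher in DGRP_892 by a log2 fold change of 4.17 in males and 8.09 in females, an interaction of -3.93 ± 0.35 (SE, adjusted p = 2.57e-17). CG15399 differed by -0.15 in males and 3.07 in females (-3.22 ± 0.14, adjusted p = 5.1e-39), and Ugt37B1 by 4.23 and 7.52 (-3.29 ± 0.29, adjusted p = 3.47e-18). In Canton-S B, over both sexes, CAH5 averaged 1.60 CPM and Ugt37B1 0.566 CPM. Males there were higher by log2 fold changes of 4.17 and 4.47, so both interactions rest on very few reads in Canton-S B females. With the authors' batch-corrected values the difference for Ugt37B1 was 0.365 (limma-trend, adjusted p = 0.0554). In the other direction, CG33109 differed by -0.86 in males and -5.53 in females (4.67 ± 1.18, adjusted p = 0.00253) and Ag5r by -0.96 and -4 (3.04 ± 0.56, adjusted p = 1.97e-05). Expression of both varied widely between libraries, and CG33109 was not past the threshold without replicate number 1 or 2. Within the deeper libraries 71 genes passed and within the shallower ones 993, and 667 to 1172 passed when a replicate number was left out.

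The time courses asked which transcripts cycle after 3 days of darkness. In Canton-S B, the clock gene per (FBgn0003068, X, 2685580 to 2692780) rose from 45.5 ± 12 CPM at CT 8 to 119.4 ± 23.1 at CT 18 (SD, n = 6), with a fitted amplitude of 0.58 log2 units. The ubiquitin ligase gene gol (FBgn0004919, 2R, 25072627 to 25084347) rose from 99.1 ± 5.21 CPM at CT 6 to 278 ± 45.7 at CT 16, and the deubiquitinase gene Usp8 from 67.2 ± 8.4 at CT 6 to 140 ± 12.7 at CT 18. Clk, which encodes a transcription activator of the clock, ran opposite, with 71.8 ± 6.45 CPM at CT 6 and 50.5 ± 7.64 at CT 22. A 24-h rhythm was called for 697 of 10894 genes (edgeR quasi-likelihood test on the coefficients of this genotype). Fitted peaks lay between 4 and 8 h for 289 of them and between 16 and 20 h for 193. A plain offset between the earlier and the later 12 h would put fitted peaks in the same windows.

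Of the 8 core clock genes, 4 were rhythmic in Canton-S B and 5 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.00819). These were per (amplitude 0.58, peak 18.7 h, adjusted p = 2.95e-18), vri (0.24, 19.3 h, 0.00124), tim (0.12, 20.2 h, 0.000498) and Clk (0.17, 6.46 h, 0.00166). The others had amplitudes of 0.13 (Pdp1, adjusted p = 0.297), 0.11 (cwo, 0.0909), 0.04 (cry, 0.836) and 0.03 (cyc, 0.802). Of 22 head output genes known from earlier work, 9 were rhythmic and 10 adjusted over the list alone (adjusted p = 0.000104). They included the feeding regulator gene to (takeout; 0.48, 8.28 h), CG11854 (0.45), Cyp4e3 (0.40, 6.64 h), the potassium channel regulator gene Slob (0.31, 18.1 h) and Cyp18a1 (0.25, 20.8 h). With a term for the earlier against the later 12 h, which overlaps the sine term (variance inflation 5.53), all 4 clock genes lost the call (adjusted p = 0.14 for per, 0.552 for tim, 0.608 for Clk and 0.958 for vri, edgeR). Within the deeper libraries tim (0.0922), Clk (0.458) and vri (0.682) lost it too. So did tim without replicate number 1 (0.052) and Clk (0.164) and vri (0.147) without number 3. Other settings gained calls. With blocks of 12 library numbers Pdp1 passed (0.00532), with these and the replicate block Pdp1 (0.00496) and cry (0.0451), and with the authors' values Pdp1 (0.0142) and cwo (0.0281, limma-trend). Also cwo passed without the 5 doubtful libraries (0.029), without Canton-S B female CT04 replicate 2 alone (0.0329), without replicate number 2 (0.0256) and with a 12-level time factor (0.000365). The output list was drawn from earlier studies of fly heads and not from these libraries.

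Among genes with at least 5 CPM, the 10 largest amplitudes in Canton-S B belonged to genes whose levels varied widely between libraries. They were whe (amplitude 2.19, peak 21.2 h), CG16826 (1.51, 21.3 h), Hsp27 (1.46, 3.75 h), Hsp70Ba (1.42, 4.04 h), CG34212 (1.36, 21.7 h), CG33109 (1.27, 21.1 h), Hsp26 (1.27, 4.32 h), CG45080 (1.25, 20.8 h), Hsp68 (1.24, 4.13 h) and Ag5r (1.17, 21 h). At CT 22 whe stood at 85.2 ± 112.8 CPM and at CT 8 at 0.092 ± 0.0918 (SD, n = 6). The small heat-shock genes and the Hsp70 genes rest on 1 library, Canton-S B female CT04 replicate 2, with Hsp68 at 4501 CPM against a median of 22.5 in the libraries outside the doubtful set. Without the 5 doubtful libraries, adjusted p was 0.999 for Hsp27, 0.701 for Hsp68, 0.71 for Hsp26, 0.796 for Hsp70Ba and 0.0583 for CG45080. Of the others, CG16826 lost the call by DESeq2 (0.0711) and without replicate number 1 (0.313), CG33109 without number 1 (0.121), and CG34212 (0.0771) and Ag5r (0.0994) without number 3. Within the deeper libraries all 10 lost it, whe at 0.274 (edgeR). The heat-shock list, with 7 of 19 genes (12 adjusted over the list alone, adjusted p = 0.00141), then had 0 genes (Fisher adjusted p = 1). Without them 626 genes were rhythmic, 572 of them among the 697, with gol at an amplitude of 0.69 and per at 0.60.

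The count for the 24-h rhythm in Canton-S B moved with the fit and with the libraries used. Within the 48 deeper libraries 82 genes were called and within the 96 shallower ones 227, of which 76 and 207 were among the 697; these sets differ in depth and in number of libraries at once. With blocks of 12 library numbers 1356 were called, and with a term for the earlier against the later 12 h, 173. Called separately, 449 genes were rhythmic in females and 518 in males, with 89 shared against 21.3 for independent lists (Fisher's exact test, two-sided p = 2.18e-32).

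**Figure D3:**
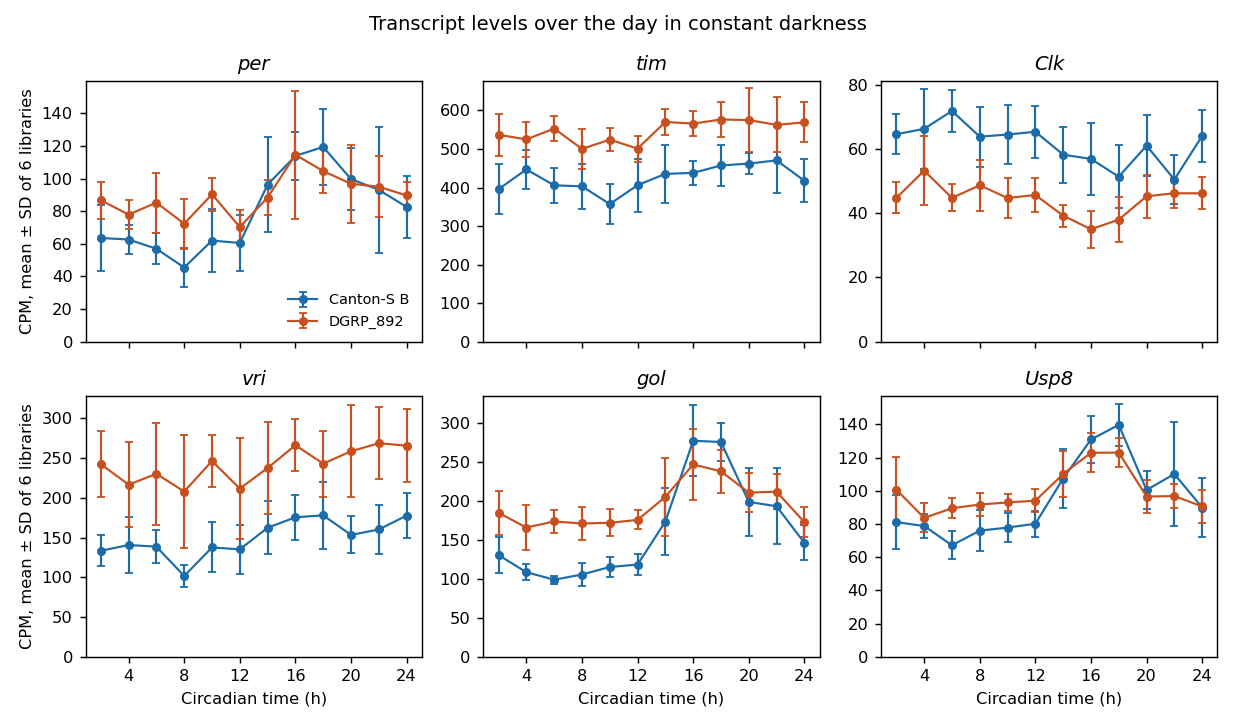
Mean CPM with SD bars of 6 libraries (both sexes) by circadian time for per, tim, Clk, vri, gol and Usp8 in Canton-S B and DGRP_892. In Canton-S B, per runs from 45.5 to 119.4 CPM and gol from 99.1 to 278; in DGRP_892 they run from 70.3 to 114.6 and from 166 to 247.

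In DGRP_892, gol rose from 166 ± 28.4 CPM at CT 4 to 247 ± 45.3 at CT 16 (SD, n = 6), and Usp8 from its lowest level at CT 4, 83.65 ± 8.71 CPM, to its highest at CT 18, with a fitted peak-to-trough ratio of 1.31. Clk ran from 35 ± 5.81 CPM at CT 16 to 53.2 ± 10.8 at CT 4, and per from 70.3 ± 10.4 at CT 12 to 114.6 ± 39.2 at CT 16. A 24-h rhythm was called for 74 genes, 20 of which were also called in Canton-S B, against 4.73 for independent lists (Fisher's exact test, two-sided p = 2.23e-08). Without the 5 doubtful libraries 8 were shared, against 1.55 for independent lists. Of the core clock genes, per (amplitude 0.20, adjusted p = 0.0414) and Clk (0.17, adjusted p = 0.00731) were past the threshold, and tim (0.08, 0.184), vri (0.13, 0.379), Pdp1 (0.07, 0.676), cry (0.06, 0.538), cwo (0.05, 0.604) and cyc (0.04, 0.616) were not. Without the 5 doubtful libraries per was at an adjusted p of 0.103 and Clk at 0.0196, and with the term for the earlier against the later 12 h they were at 0.814 and 0.466 (edgeR).

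Among genes with at least 5 CPM, the largest amplitudes in DGRP_892 were CG34220 (1.21, peak 22.7 h), the female-biased gene Obp99a (0.92, 18.5 h), the calcium-binding protein gene Scp1 (0.64, 18 h), the cuticle protein gene Cpr11B (0.34, 16.8 h), hry (0.32, 4.48 h), to (0.30, 8.63 h), lncRNA:CR45997 (0.29, 9.29 h), gol (0.24, 17.9 h), the carbonic anhydrase gene CAH9 (0.21, 19.6 h) and per (0.20, 18.8 h). The amplitude of Obp99a was 0.447 in DGRP_892 females and 1.43 in DGRP_892 males. Over both genotypes this gene averaged 0.866 CPM in males and 81 CPM in females, so its larger male amplitude rests on very few reads. Of the 74 genes, 42 had peaks between 20 and 24 h, and 3 of 12 gut genes were among them (epsilonTry, Jon99Cii and LysD; 6 adjusted over the list alone; Fisher adjusted p = 0.00165). These rest on few libraries. In DGRP_892 male CT22 replicate 2, the gut list stood 4.95 log2 units above its median and the testis and accessory gland list 5.46, and in Canton-S B male CT22 replicate 1 they stood at 3.93 and 6.43. The gut list also stood 2.86 above in DGRP_892 male CT10 replicate 2 and 2.56 in DGRP_892 female CT22 replicate 1. The digestive genes were at low levels even there: Jon25Biii at 10.2, LysD at 15.6 and epsilonTry at 4.15 CPM in the first of these, and CG34220 at 324 against a highest value of 8.5 outside the doubtful set.

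Without these 4 libraries and the heat-shock library, 27 genes were rhythmic in DGRP_892, 25 of them among the 74, and the gut list had 0 (Fisher adjusted p = 1). CG34220 was then at an adjusted p of 0.669, Scp1 at 0.0512 and to at 0.0525. The calls of Obp99a, Scp1, Cpr11B, hry and Clk ended whichever replicate number was left out (hry 0.0873, 0.186 and 0.342, edgeR adjusted p), and each other named gene except gol lost its call without at least 1 number. With the authors' batch-corrected values Obp99a (0.855), Scp1 (0.454), Cpr11B (0.119) and hry (0.296) lost it as well (limma-trend). Leaving out DGRP_892 male CT22 replicate 2 alone gave 26 genes. The count was 48 within the deeper and 9 within the shallower libraries (16 and 8 of the 74), 32 by DESeq2 and 14 with the authors' batch-corrected values. It was 15 with the term for the earlier against the later 12 h and 151 without a filter on low counts.

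**Figure D4:**
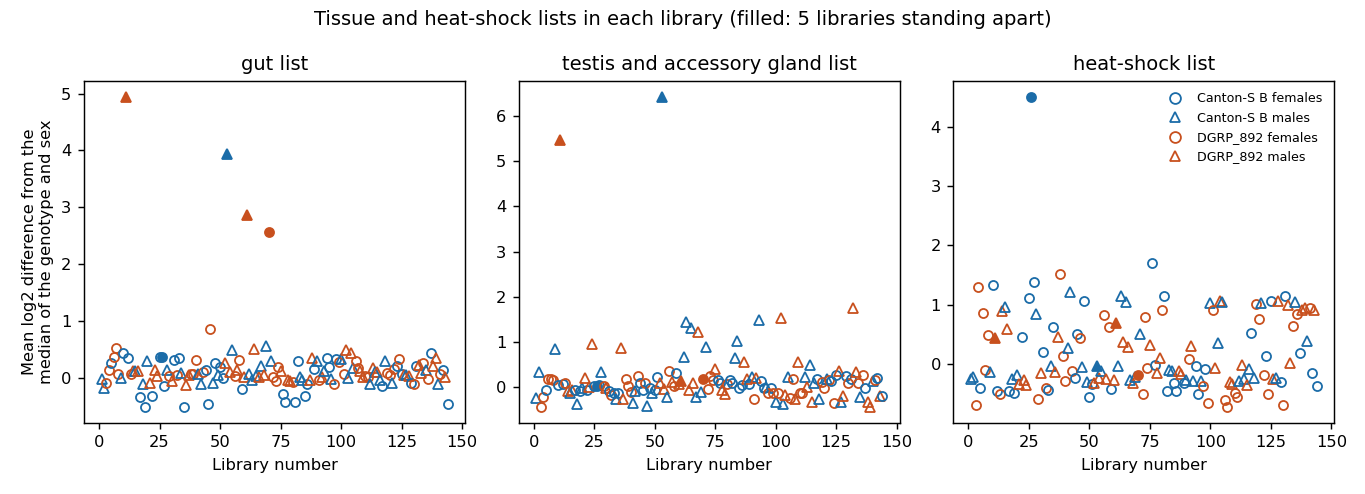
Mean log2 score of the gut, testis and accessory gland, and heat-shock lists, relative to the median of the same genotype and sex, for the 144 libraries by library number. The 5 filled points are the doubtful libraries, with gut scores of 2.56 to 4.95 in 4 of them and a heat-shock score of 4.51 in the other.

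The 10 genes named for genotype by time were chosen by the size of that difference. Some other well-called rhythms of Canton-S B did not pass this test. Without the 5 doubtful libraries, Slob was at an adjusted p of 0.0609 and to at 0.994 (genotype by time, edgeR). For gol the amplitude was 0.68 in Canton-S B and 0.24 in DGRP_892 (genotype by time, adjusted p = 1.33e-08), for per 0.58 and 0.20 (adjusted p = 0.00227) and for Usp8 0.42 and 0.19 (adjusted p = 0.00754). The blue-light opsin gene Rh5 had 0.16 and 0.07 (adjusted p = 0.0168) and the photoreceptor matrix gene eys 0.23 and 0.04 (adjusted p = 0.00787). FBgn0033981 had 0.35 and 0.12, CG5853 0.28 and 0.05, CG31300 0.22 and 0.04, CG33110 0.18 and 0.06 and CG14186 0.20 and 0.03, with adjusted p from 0.00439 to 0.0176. All 10 had the larger amplitude in Canton-S B. This test covers amplitude and peak time together. Fitted peaks in Canton-S B and DGRP_892 lay far apart for Rh5 (6.99 and 17.5 h) and CG33110 (20.5 and 4.51 h). They also did for CG31300 (6.35 and 14.2 h) and CG5853 (7.14 and 0.343 h). These genes had no called rhythm in DGRP_892 (edgeR adjusted p from 0.469 to 0.755), so their peaks there are uncertain. Among the other named genes the widest gap was that of Usp8 (18.1 and 16.8 h). When a replicate number was left out, 9 of the 10 lost the call at least once and only gol kept it. For per the adjusted p was 0.298 without number 1 and 0.132 without number 2, and for Usp8 it was 0.2, 0.0711 and 0.447 without numbers 1, 2 and 3 (edgeR). Within the deeper libraries the same 9 lost it (per 0.678) and gol was at 0.0138. Genotype by time was called for 16 genes in all, and without the 5 doubtful libraries for 15, of which 12 were among the 16 and all 15 had the larger amplitude in Canton-S B. The lists with a member past the threshold (per, Usp8, Rh5 and the gut gene Jon99Cii) did not pass (Fisher adjusted p = 0.195 each).

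Over the 6 series of each genotype, the amplitude of per was 0.594 ± 0.129 in Canton-S B and 0.225 ± 0.0967 in DGRP_892 (SD, n = 6 each; exact permutation p = 0.00216, adjusted p = 0.0173 over 8 clock genes). That test ignores the pairing by sex and replicate number. Paired, all 6 pairs were smaller in DGRP_892, with a mean difference of -0.369 ± 0.177 (SD). The exact sign-flip permutation p of 0.0312 is the smallest that 6 pairs allow, and for a single gene among 8 it adjusts to 0.25, so the paired test could not pass and decides nothing after adjustment. In the unpaired test the other 7 clock genes gave an adjusted p of 0.675 or more. Genes chosen as rhythmic in Canton-S B have amplitudes that are biased upward there. When genes were chosen in 1 sex of Canton-S B and their amplitude along the chosen peak was measured in the other sex, the median over genes averaged 0.0639 ± 0.0343 in Canton-S B and 0.0326 ± 0.0291 in DGRP_892 (SD, n = 6; exact permutation p = 0.108, unpaired). Paired by sex and replicate number, a test added after the unpaired result was seen, all 6 pairs were smaller in DGRP_892, with a mean difference of -0.0314 ± 0.0279 (SD; exact sign-flip permutation p = 0.0312, the smallest possible). Without the 5 doubtful libraries it was -0.0331 ± 0.0332 (p = 0.0312, exact). This choice still favours smaller values in DGRP_892. Genes were chosen only in Canton-S B, and any other peak time in DGRP_892 lowers its value along the Canton-S B peak. The reverse choice, of genes rhythmic in DGRP_892, was not run. The genotype-by-time count was 43 with blocks of 12 library numbers, 3 with a 12-level time factor and 33 without Canton-S B male CT22 replicate 1. With the term for the earlier against the later 12 h it was 0 by edgeR (313 at an unadjusted p under 0.05), and no other tool was run with that term. It was 8 within the deeper and 8 within the shallower libraries, of which 1 and 5 were among the 16.

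**Figure D5:**
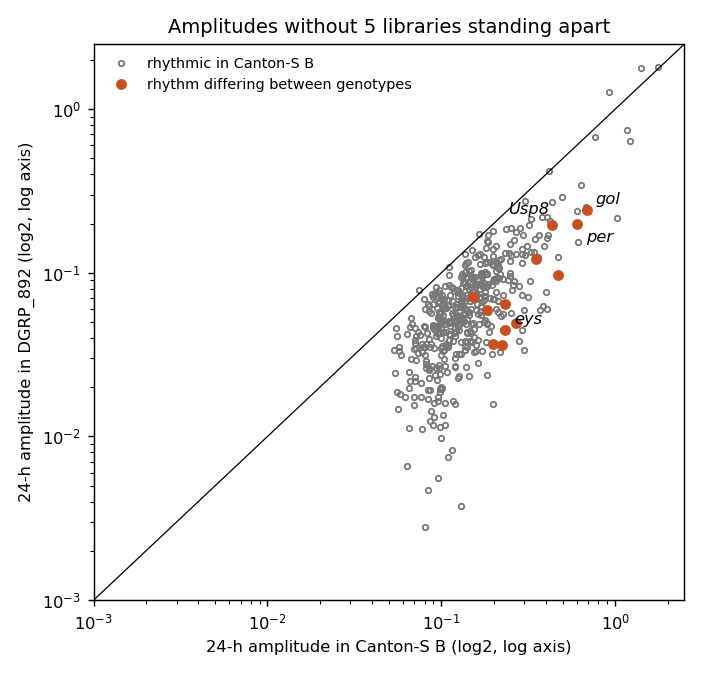
Fitted 24-h amplitude (log2, logarithmic axes) in DGRP_892 against Canton-S B, without the 5 doubtful libraries, for rhythmic genes with at least 5 CPM, 1 point per gene. For gol the amplitudes are 0.69 and 0.24 and for per 0.60 and 0.20 in Canton-S B and DGRP_892.

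Peak times asked whether the long-period line was delayed. The peak of per lay at 18.6 ± 1.2 h in Canton-S B and 18.7 ± 2.32 h in DGRP_892 (SD, n = 6 series; exact permutation p = 0.948). Clk peaked at 6.61 ± 1.23 h and 4.28 ± 1.64 h, a difference of -2.32 h (exact permutation p = 0.026, adjusted p = 0.208 over 8 clock genes), which was not past the threshold after adjustment. Paired, it was -2.29 ± 1.42 h (SD, 6 pairs) at the smallest possible exact sign-flip p of 0.0312, where adjustment over 8 genes could not have passed, so an earlier Clk peak in DGRP_892 stays open. The remaining clock genes had adjusted p from 0.944 to 0.948. Over per and Clk, the 2 clock genes past the threshold in both genotypes, the median difference of fitted peaks was -1.12 h. Over the 20 genes rhythmic in both genotypes, the median difference was -0.0815 ± 1.3 h (SD over 6 pairs of series; exact sign-flip permutation p = 0.844). Over the 697 genes rhythmic in Canton-S B it was 0.851 ± 1.07 h (exact sign-flip permutation p = 0.156). A delay common to these genes was not detectable against a spread of this size. Most of the 20 genes rest on the doubtful libraries, since without them 8 genes were called in both genotypes. A male CT22 library with high gut and testis scores in each genotype could draw fitted peaks together. Without the doubtful libraries, the same 20 genes gave 0.0281 ± 0.817 h (SD over 6 pairs of series, exact sign-flip permutation p = 0.938). A common delay was not detectable there either. The 20 genes had been chosen with these libraries, however, and a delay within this spread stays open. Of the best-called shared rhythms, Usp8 peaked earlier in DGRP_892 by 1.11 ± 0.59 h (SD, 6 pairs, exact sign-flip permutation p = 0.0312, the smallest possible, unadjusted). For gol the difference was -0.24 ± 0.743 h (exact sign-flip permutation p = 0.406). The unpaired exact permutation test, seen first, gave p = 0.156 for Usp8 and 0.747 for gol, so an earlier Usp8 peak stays open.

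In the test of sex by time, the rhythm differed between males and females in 65 genes, and with the replicate block in 43. The 5 with the largest distances and at least 5 CPM were CG34220 (amplitude 0.20 in females and 1.97 in males, adjusted p = 0.000564), CG34034 (0.12 and 0.97, adjusted p = 0.05), CG7203 (0.73 and 0.07, adjusted p = 0.0365), CROT (0.04 and 0.22, adjusted p = 0.0256) and Papss (0.16 and 0.07, adjusted p = 0.0401). All 5 lost the call without replicate number 1 and without number 2. The male amplitude of CG34034 was 1.96 in Canton-S B, where the gene averaged 0.371 CPM over both sexes. In DGRP_892, where it averaged 5.67 CPM, the male amplitude was 0.0614. CROT encodes a carnitine acyltransferase and Papss a sulfate donor synthase. Most of these calls moved with the libraries that had high gut and testis scores: without the 5 doubtful libraries 2 genes were called, and without DGRP_892 male CT22 replicate 2 or Canton-S B male CT22 replicate 1 alone, 6 and 5. The count was 10 within the deeper and 3 within the shallower libraries, 42 by DESeq2, 0 with the authors' batch-corrected values by limma-trend (381 at an unadjusted p under 0.05) and 224 without a filter on low counts. A difference of rhythms by genotype and sex together was called for 0 genes by edgeR, with 358 at an unadjusted p under 0.05, and no other tool was run for it.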

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

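Of the tests weighed here, those on single libraries and on the other CT22 libraries were chosen after seeing the result, while those on the accessory gland, amplitudes and yolk genes were written before their values were computed, though after the patterns had been seen. The groupings at the end had been planned. The amplitude tests were written after the counts with a 28-h cosine and with a day-part term had been seen.

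3 of 37 groups of series held a value far from the others, where 1.85 are due by chance. The Clk amplitude of Canton-S B females of replicate 3 was 0.412, against 0.0622 to 0.179 in the other 5 series. The Usp8 amplitude of the same series was 0.602, against 0.346 to 0.434. The projected amplitude of DGRP_892 males of replicate 1 was 0.0888, against 0.00327 to 0.0295.

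For some genes the genotype difference depended on sex (edgeR, adjusted p for the interaction). Male minus female genotype effects on the log2 scale were -3.93 for CAH5, -3.29 for Ugt37B1, -3.22 for CG15399, 4.67 for CG33109 and 3.04 for Ag5r. Among the sex-biased genes they were 1.54 for Obp99b (adjusted p = 6.87e-09), 0.306 for Cyp4d21 (0.0397), -0.668 for TotX (0.00289) and -0.454 for Cyp313a1 (0.000276). Female-biased genes gave -1.98 for Yp1 (0.000599), -2.21 for Yp2 (0.000475), -2.04 for Yp3 (6.34e-06), -1.88 for Obp99a (0.00858), -1.31 for asRNA:CR45601 (0.00854), 1.71 for FBgn0028519 (0.000928), 0.746 for asRNA:CR45046 (0.0222) and 1.40 for fit (6.31e-07). The yolk gene values rest partly on low male levels, and those of CAH5 and Ugt37B1 on very few reads in Canton-S B females. In males the median Yp1 level was 0.32% of the female level in Canton-S B and 0.101% in DGRP_892. Whether female material in male libraries shaped these interactions was not tested.

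The rhythm differed between genotypes by a distance of 0.44 for gol, 0.378 for per, 0.291 for CG5853, 0.247 for Usp8, 0.242 for CG31300, 0.24 for FBgn0033981, 0.225 for Rh5, 0.221 for CG33110, 0.191 for eys and 0.161 for CG14186. It differed between the sexes by 1.96 for CG34220, 1.00 for CG34034, 0.806 for CG7203, 0.243 for CROT and 0.228 for Papss.

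In DGRP_892, 35 genes chosen by an amplitude of at least 1 and a peak between 20 and 24 h, of which 3 are in the gut list and the others in no list, may owe their calls to body tissue in single libraries. Without the 5 doubtful libraries 1 (Mur18B) stayed past the threshold, with its peak then at 14.9 h, but this is partly built in, since the libraries were picked by scores such as those of gut and testis, and it does not show the tissue of the unlisted genes. Accessory gland tissue was likely present in the 2 male CT22 libraries, where 42 Acp and Sfp genes outside the lists stood at medians of 3.4 and 4.84 log2 units above the male median. A daily rhythm of the gut list in DGRP_892 males is not supported, as the other 2 CT22 male libraries of DGRP_892 had gut scores of only 0.172 and -0.137. The doubtful libraries with high gut scores were mostly from CT22 (4.95, 3.93 and 2.56, with 2.86 at CT10). A link with that collection time therefore stays open. Heads also express 7 of the 12 gut genes measured at 1 CPM or more, and 3 of the 12 are in another list.

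The smaller amplitudes in DGRP_892 of the 16 genotype-by-time genes gave a ratio of 0.492 ± 0.084 (SD over 6 pairs of series), which is biased downward because the genes were chosen for the difference. A 28-h cosine gave 0.46 ± 0.0632 and a term for the earlier against the later 12 h 0.606 ± 0.143, but on genes chosen this way neither value rules out a longer period or an offset between the day parts. Whether an offset is the cause cannot be told. That term ended all 16 calls, but the ratio with it was still 0.606. The sine term shares 81.9% of its variance with it (variance inflation 5.53), which by itself makes calls harder to reach. Larger spread in DGRP_892 was not seen (residual SD ratio 0.811 ± 0.105), and loss of synchrony among the flies of a library was not tested.

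Yolk protein mRNA in male libraries could come from female heads among the male ones, but this could not be told. The share of 4 other female-biased genes rose with the Yp1 share with a median slope of 0.744 and an SD of 1.74 over 8 slopes. In Canton-S B these were 4.93 ± 1.76 (SE) for CG10814, 2.09 ± 0.194 for fit, 0.999 ± 0.165 for Obp99a and 0.458 ± 0.0931 for rost, and in DGRP_892 -1.03 ± 3.65, 0.636 ± 1.85, 0.851 ± 0.112 and 0.46 ± 0.433. Runs explained 12.1% of the variance over 72 male libraries. Every run held female libraries of both genotypes, so reads exchanged within runs could raise the male level in all runs alike. The test therefore cannot exclude exchanged reads as a source of the typical male level. The highest yolk share in a male library was 9.63% of the female level, and the median 0.32% in Canton-S B. No biological explanation was tested.

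Regrouping the libraries at random (real grouping and 99 others, limma-trend) tested whether such counts could arise by chance. At least as many genes as in the real grouping were found in 1 of 100 groupings for genotype (7378 genes, highest other 3), 1 for sex (7357, 1487), 1 for genotype by sex (1435, 2), 1 for the Canton-S B rhythm (547, 313) and 1 for the DGRP_892 rhythm, where the counts were 3 and 2. For genotype by time it was 2 of 100, with 12 genes in the real grouping and 2851 in the highest other. In that grouping, runs of 24 library numbers explained 9.14% of the terms against 2.06% in the real one and 4.47% in the median grouping. Another grouping reached 13.7%, and the second-highest count was 1 gene, so the source of the 2851 calls is left open. For sex by time it was 100 of 100, which was fixed because limma-trend called 0 genes in the real grouping, so nothing follows for the 65 genes of edgeR. For the DGRP_892 rhythm, limma-trend called 3 genes where edgeR called 74, so little follows for those 74. For genotype and sex, the real difference stayed in the regrouped libraries as spread within groups, so low counts were largely built in. Those regroupings also parted only 36 to 58 (genotype) and 30 to 58 (sex) of the 72 replicate pairs parted in the real grouping. The genotype and sex results therefore decide nothing about chance.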

How the results depend on the processing

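The tests without doubtful libraries, within depth classes and with combined blocks were chosen after seeing the result. Of genes named for genotype and sex, all 320 and all 300 values kept their direction and side of the threshold; these genes had been chosen for large folds of 1 sign in all pairs of groups, which favours this. For genotype by sex 65 of 70 did, for the Canton-S B rhythm 306 of 375, for DGRP_892 281 of 373, for genotype by time 301 of 357 and for sex by time only 34, fewer than did not. Where no reason is given below, the cause was not tested.

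Counts for the genotype effect ran from 3605 with ERCC scaling to 8155 (main 7363). ERCC totals vary more between libraries, but whether this lowered the count was not tested. For the sex effect, counts ran from 4304 in the deeper libraries, which are fewer and were fitted with cosines instead of group means, to 7678 (main 7162). With the authors' batch-corrected values, 345 and 94 genes were past 2-fold instead of 830 and 298; values, tool, genes and added constant all changed, and the cause was not tested. Genotype by sex gave 1399, 667 to 1172 without a replicate number and 71 in the deeper libraries. These hold fewer samples and were fitted with cosines instead of group means. The Ugt37B1 interaction reversed to 0.365 with the authors' values (main -3.29). The main value rests on very few reads in Canton-S B females, and the cause of the reversal was not tested.

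The 24-h rhythm in Canton-S B gave 697 genes, 216 to 678 without a replicate number (fewer samples), 1356 with blocks of 12 library numbers, 1237 with these blocks and without the doubtful libraries, and 1505 with both blocks. It gave 173 with the day-part term, 82 in deeper and 227 in shallower libraries, which hold fewer samples. It gave 774 without DGRP_892 male CT22 replicate 2.

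The 24-h rhythm in DGRP_892 gave 74 genes, 151 without a filter, 32 by DESeq2, 14 with the authors' values and 15 with the day-part term. It gave 12 to 47 without a replicate number, 48 in deeper and 9 in shallower libraries, 27 without the doubtful libraries, and 39 with blocks besides. Without DGRP_892 male CT22 replicate 2 it gave 26, and without Canton-S B male CT22 replicate 1 it gave 1.3e+02 (to 2 digits).

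Genotype by time gave 16 genes, 43 with blocks, 55 with both blocks, 29 with blocks and without doubtful libraries, and 33 without Canton-S B male CT22 replicate 1. It gave 7 to 10 without a replicate number, 8 in deeper and 8 in shallower libraries, 3 with a 12-level time factor and 0 with the day-part term (edgeR, 313 unadjusted). A 28-h cosine in DGRP_892 was not run here, because equal coefficients at different periods are not equal rhythms.

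In sex by time, 65 genes were called, 224 without a filter, 42 by DESeq2, 43 with the replicate block, 37 with both blocks and 4 with the day-part term. It gave 2 to 15 without a replicate number, 10 in deeper and 3 in shallower libraries, 2 without the doubtful libraries, and 6 and 5 without DGRP_892 male CT22 replicate 2 or Canton-S B male CT22 replicate 1, and 95 without DGRP_892 male CT10 replicate 2. It gave 0 with the authors' values (limma-trend, 381 unadjusted) and 0 with blocks and without doubtful libraries (edgeR, 387 unadjusted).

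Median phase differences over shared genes, -0.0815 h, were reversed without replicate 2 (0.33 h; range -0.38 to 0.33 h without a replicate number), with the 28-h cosine (0.127 h) and without the doubtful libraries (0.0281 h), and the cause was not tested. The value without the doubtful libraries was taken over the same 20 genes. For the clock genes the median differences stayed between -1.81 and -0.791 h. Of 26 lists, 5 passed for genotype, 0 in camera with an estimated correlation and 19 by fry, and for sex 12, 6 and 23, since the estimated correlation widens camera's null and fry ignores other genes. At the depth of these libraries, simulated differences of 0.2 in genotype by time were found for 16% of genes. That simulation had 1 common dispersion and no structure shared between libraries.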

Other observations

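The values in this part were chosen after seeing the result, and no test was run on them beyond those named. Peaks of rhythmic genes in Canton-S B were most frequent in 2 windows. A plain offset between the earlier and the later 12 h would put fitted peaks in these same windows. With a term for it far fewer genes were called, so the windows need not reflect peak times. Without the doubtful libraries, 258 of 626 genes (41.2%) peaked between 4 and 8 h and 180 (28.8%) between 16 and 20 h, whereas 92 (14.7%) peaked between 8 and 12 h, 57 (9.11%) between 20 and 24 h, 29 (4.63%) between 0 and 4 h and 10 (1.6%) between 12 and 16 h. Slob (amplitude 0.32, peak 18.2 h, edgeR adjusted p = 1.97e-10 without these libraries) was among the later genes, with gol and per. The median amplitude of these 626 genes was 0.162 in Canton-S B and 0.0693 in DGRP_892, and 618 had the larger amplitude in Canton-S B, where they had been chosen. Genes chosen in DGRP_892 went the other way: of the 27 rhythmic there without these libraries, 8 had the larger amplitude in Canton-S B (medians 0.345 in Canton-S B and 0.837 in DGRP_892). Some of the 27, such as gol (194 CPM in DGRP_892), were well expressed. Many others were near the floor there, such as BaraA1 (0.683 CPM, amplitude 9.02), Pxd (0.299 CPM, 1.77) and CG13044 (0.08 CPM, 2.71). Such amplitudes rest on very few reads, so these medians do not show larger rhythms in DGRP_892. With all libraries the larger amplitude lay in Canton-S B for 17 of the 74 genes rhythmic in DGRP_892, and for 12 of the 20 rhythmic in both. The 74 include the 35 late-night genes that may owe their calls to body tissue in single libraries. The cuticle gene dy, chosen after its values were seen, was rhythmic in both genotypes (adjusted p = 2e-13 in Canton-S B and 5.67e-10 in DGRP_892, edgeR without the doubtful libraries). Its mean level was low, at 0.760 CPM in Canton-S B and 3.42 CPM in DGRP_892.

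Heat-shock scores followed the replicate number. Their median was 0.911 in the 48 libraries of replicate 2, against -0.27 in replicate 1 and -0.223 in replicate 3. A score above 1 was found in 19 libraries of replicate 2, 0 of replicate 1 and 2 of replicate 3. The highest library was Canton-S B female CT04 replicate 2, with Hsp68 at 4501 CPM and Hsp26 at 2632 CPM, against medians of 22.5 and 8.97 CPM outside the doubtful set.

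The sperm gene Mst87F was low outside the doubtful libraries. It reached 23.4 CPM in Canton-S B male CT22 replicate 1 and 4.82 in DGRP_892 male CT22 replicate 2, with a highest value of 0.975 elsewhere. ERCC transcripts took 0.411% ± 0.184 of counts in Canton-S B and 0.391% ± 0.186 in DGRP_892 (SD, n = 72 each). Their share ran from 0.256% ± 0.047 in the first run of 24 library numbers to 0.728% ± 0.154 in the sixth (SD, n = 24 each).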
